A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

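Poly(A)+ RNA of fission yeast (Schizosaccharomyces pombe) was sequenced from 2 strains of mating type h-, grown in rich YES medium to log phase. One strain carried wild-type pla1 and the other the active-site mutation Y86D of pla1, the gene of the nuclear poly(A) polymerase, each linked to the kanMX drug marker. Each strain was represented by 3 libraries. The series design calls them replicate experiments and does not say whether they were separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. RNA was purified with hot acid phenol, and libraries were made with a stranded Illumina kit and sequenced as paired ends, per the labels' protocols.

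The count table holds whole-number read counts per annotated feature, deposited without normalization. HISAT2 2.1.0, SAMtools, HTSeq 0.10.0, DESeq2 and DESeq are named in the submitters' processing notes, with genome build ASM294v2. The strand setting of the counting, the annotation release and the handling of reads with several alignments are not given in the sources used here. Counts of near-identical copies (tlh, Tf2 and wtf genes), of overlapping features and of antisense RNAs are therefore uncertain. Per the file headers, the second deposited table holds a DESeq2 comparison of the strains. Its signal columns are means of counts divided by size factors, made by the authors. Its log2 columns are the fold change and its standard error, as computed by the authors. Its Wald statistic is a score computed by the authors, and its p-value columns, raw and adjusted, are also as deposited. From this table only the calls and fold changes were compared with the fit made here.

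The count table held 6988 features and no row without a feature. Of these, 6836 (97.8%) matched the RefSeq annotation of assembly ASM294v3 by systematic identifier. That assembly is not the build of the deposited files, so it served only for names, feature classes, the order of neighbours and transcript sequences, and no coordinates are printed. Gene names came from the authors' deposited table, and 2 names stored there as numbers were replaced from the reference. The total counts per library were 19275152, 21849845 and 21754151 for pla1-WT replicates 1, 2 and 3, and 17594840, 18358442 and 21173765 for pla1-Y86D replicates 1, 2 and 3. The 36 mitochondrial features were listed at 0 in all 6 libraries, so nothing is reported on the mitochondrial list. Pairs of libraries of one strain differed by more than sampling noise (chi-square per degree of freedom from 1.63 to 4.83), and no library was treated as a repeat of another.

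Features were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, libraries were scaled by TMM (trimmed mean of M-values), and a robust quasi-likelihood model with strain as the only term was fitted to all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 6267 features tested, and an adjusted p under 0.05 was called. Fold changes are pla1-Y86D over pla1-WT on the log2 scale, and their standard errors were derived from the fold change and its F statistic. Levels are CPM, counts relative to the TMM-scaled library total, as mean ± SD of 3 libraries. Shares of counts by feature class were compared with a two-sided exact permutation test, whose smallest p with 3 libraries against 3 is 0.1. Classes among the calls were compared with Fisher's exact test, two-sided, against all features tested.

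Before the data were examined, 26 gene lists were written from general knowledge. Lists with at least 5 tested members were compared with all other features by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists tested. Camera was repeated with an estimated correlation, and fry was run as another test. The lists covered Mmi1 and MTREC meiotic mRNAs, the phosphate regulon, regulatory lncRNAs, middle meiotic and early mating genes, P-cell genes, the cleavage and polyadenylation machinery, Mmi1, MTREC and exosome subunits, inositol pyrophosphate regulators, iron uptake and iron-using genes, stress and heat shock genes, ribosomal proteins, ribosome biogenesis, histones, glucose, nitrogen and thiamine genes, flocculation adhesins, Tf2 and wtf families, ncRNAs, snoRNAs and snRNAs, the mitochondrial genome and genes named mug or meu. List members mamRNA, mat1-Pc, mat1-Pm, mat1-Pi, utp1, dbp4, nop7 and inda1 were not matched and are not analysed here. Members were matched by symbol, and hrs1, clp1, hrp1 and pck1 turned out to be other genes than the lists meant. The lists as written were kept for the main tests. A corrected version, made after the results were seen, put mcp6 in place of hrs1 and left out the other 3.

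Genes to be named were set by a rule written in advance. It took pla1, then the 12 protein-coding genes with the largest increase and the 8 with the largest decrease among those called, with a mean count of at least 50 and no overlap between the strains' libraries. It also took every tested phosphate regulon gene and regulatory lncRNA, the 8 Mmi1 list members with the smallest p, up to 3 called members of each other list, and the 4 ncRNAs with the largest increase and the 2 with the largest decrease within the same limits on call, count and overlap. An ncRNA under the count limit reached a log2 fold change of 7.75 and was not named.

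The fit was tested on simulated data drawn from the pla1-WT means and the real library sizes for this comparison, with 6163 genes tested. It called 82.0% of 50 genes changed 1.2-fold, 96.0% of 50 changed 1.5-fold, and all 50 genes at each of 2-fold and 4-fold. It also called 0.30% of the 5963 unchanged genes. Changes were planted only in features with a mean count of at least 50, so recovery at lower counts was not tested. Most simulated genes were unchanged, unlike the real features, so scaling under broad change was not tested either. The alternatives tried were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, protein-coding features alone, an adjusted p under 0.01, the replicate number as a block, and leaving out each library in turn. Resampling tests used Python with SciPy.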

Results

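The data comprised stranded poly(A)+ RNA-seq counts from 3 libraries of a fission yeast strain with wild-type pla1 and 3 of a strain with the pla1-Y86D mutation. Pla1 is the nuclear poly(A) polymerase that adds the tail to mRNA 3' ends. The series title names a class of mRNAs, those targeted by Mmi1 and MTREC, as raised in the mutant. Mmi1 binds meiotic mRNAs in growing cells, and MTREC is the complex that passes such RNAs to the nuclear exosome for decay. Totals ranged from 17594840 to 21849845 counts per library. The first principal component held 91.0% of the variance and separated the strains, and the biological coefficient of variation was 2.42%.

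The pla1 mRNA (SPBC646.04) itself was slightly higher in the mutant, at 47.4 ± 0.85 CPM against 36.6 ± 0.96 CPM (SD, n = 3 per strain). Its log2 fold change was 0.37 (SE 0.045, edgeR adjusted p = 2.6e-09). A point mutation need not change the level of its mRNA, so this value does not check the labels.

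Most of the transcriptome differed between the strains, largely by small amounts. Of 6267 features tested, 2512 were higher and 2574 were lower in pla1-Y86D by edgeR's quasi-likelihood test. Both counts are relative to the TMM scaling, which cannot show a change shared by most mRNAs. The median size of a called change was 0.39 on the log2 scale. Changes of at least 2-fold ran mainly upward, with 565 features higher and 149 lower, and at 4-fold or more there were 149 higher and 8 lower. In the authors' deposited table, 4781 features passed an adjusted p of 0.05, and 4727 of them were also called here, all in the same direction.

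The protein-coding genes with the largest increases included ddr48 (SPAC23H3.15c), annotated as DNA damage-responsive, which rose from 10.4 ± 1.1 to 299.1 ± 8.4 CPM (log2 fold change 4.85, SE 0.043). The proteasome regulator gene fub2 (SPBP4G3.03) rose by 4.63 on the log2 scale. Increases of 4.41 for SPBPB21E7.02c, 4.12 for the O-methyltransferase gene cmt2 and 3.07 for the enolase gene eno102 came from features with identifiers of one cosmid. The first of these, SPBPB21E7.02c, was at 4.97 without pla1-WT replicate 2 and at 3.90 without pla1-WT replicate 3. SPCC737.04 and meu27, both of the UPF0300 family, rose by 3.99 and 3.35. The small heat shock protein gene hsp9 rose from 176 ± 5.8 to 1941 ± 37 CPM, a log2 fold change of 3.46. The other genes of this group were mug108 (3.46), lsd90 (3.25), meu13 (3.22), which acts in meiotic recombination, and SPAC4F10.17 (3.13). All 12 had an edgeR adjusted p of 2.2e-07 or less.

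Among the largest decreases, SPBPB7E8.01, a predicted GPI-anchored protein gene, fell from 284 ± 12 to 45.3 ± 0.23 CPM (log2 fold change -2.65). The malic enzyme gene mae2 fell from 1218 ± 29 to 285 ± 3.9 CPM (log2 fold change -2.10). Decreases also reached SPAC5H10.07 (-2.50), the spermidine transporter gene mfs3 (-2.36), abp2 (-2.29), the thioesterase gene the4 (-2.12) and SPAC1039.02 (-1.93). The helicase gene tlh2 had a log2 fold change of -2.85 (SE 0.76, edgeR adjusted p = 0.0237). Its control libraries ranged from 4.39 to 15.2 CPM, and it has a near-identical copy. Its edgeR adjusted p rose to 0.0735, 0.0751 and 0.0751 without pla1-Y86D replicate 1, 2 and 3, and by limma-voom it was 0.0557. Without pla1-WT replicate 3 its log2 fold change was -2.20.

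The Mmi1 and MTREC list of meiotic mRNAs had 17 of 18 tested members higher in the mutant, 13 of them at least 2-fold, with a median log2 fold change of 1.57. One of the 17, hrs1 (0.22), was matched by its symbol to a histidine-tRNA ligase gene, which is not a meiotic mRNA. The gene meant was mcp6 (1.24, looked up after the lists had been tested), and with it in place of hrs1 the list had 17 of 18 higher, 14 at least 2-fold, and a camera adjusted p of 2.79e-19 (0.0667 with an estimated correlation). The cohesin gene rec8 rose from 10.6 ± 0.27 to 76.4 ± 0.52 CPM (log2 fold change 2.85), and mei4, a forkhead transcription factor of meiosis, from 17.0 ± 0.95 to 121.7 ± 5.3 CPM (2.83). The log2 fold changes were 2.67 for mug10, 2.62 for spo5, 2.53 for mug8, 1.59 for mug45, 1.56 for mcp7 and 1.41 for the recombination gene rec10. The member not called, meu6, had a log2 fold change of -0.08 (edgeR adjusted p = 0.408) and was named after its value was seen. Because the series title names this class as raised, its direction is not independent evidence. Camera gave an adjusted p of 9.15e-19 for the list as written, and an adjusted p of 0.0936 with an estimated correlation.

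**Figure D1:**
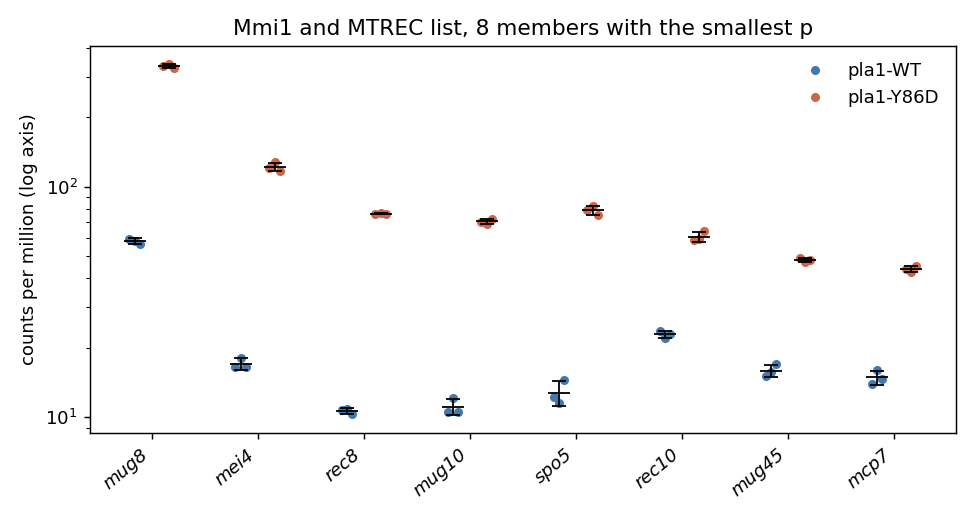
Read counts in CPM on a log axis for the 8 members of the Mmi1 and MTREC list with the smallest p. Points are the 3 libraries of each strain, and bars show the mean and SD. For rec8 the means were 10.6 and 76.4 CPM in pla1-WT and pla1-Y86D.

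Of the 112 tested genes named mug or meu (meiotic upregulated genes), 62 were higher and 21 lower, and 29 rose at least 2-fold. This list includes mug8 and mug10 above and mug147, whose log2 fold change was 2.59. Its camera adjusted p was 0.000376, with an adjusted p of 0.116 under an estimated correlation. Middle meiotic genes that depend on Mei4 had 7 members higher and 2 lower of 12, with a median of 0.12 and a camera adjusted p of 0.572. Among them meu14 rose by 1.27, the spore wall gene isp3 by 0.73 and the septin gene spn7 by 0.47. Early mating genes were divided, 5 higher and 5 lower of 14 (camera adjusted p = 0.898). In that list rep1, an activator of early meiotic transcription, rose by 1.69, whereas the mating regulator gene ste11 had a log2 fold change of -0.78 and the pheromone gene mfm2 of -0.95. The median of the early mating list was -0.05 although camera ranked it upward. Genes listed as specific to the opposite mating type were measured as a marker of mixed cultures, and 3 were higher and 1 lower of 4. These were map2 (0.58), map1 (0.32) and map3 (-0.69) among the 3 named. The remaining member, sxa1 (0.07), was named after its value was seen. It was at 402 ± 10 CPM in pla1-WT and 422 ± 7.9 CPM in pla1-Y86D, far above the others. The mat1-P genes were not matched, so this list gives no clear reading on mixed cultures.

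Long noncoding RNAs that regulate phosphate genes or meiosis were higher in 4 of 5 cases. The meiotic sme2 RNA rose from 52.8 ± 1.2 to 187 ± 4.6 CPM (log2 fold change 1.83), and nam1 rose by 2.09. At the pho1 locus the upstream RNA nc-pho1 (prt) rose from 27.5 ± 1.6 to 109.5 ± 2.4 CPM (2.0 on the log2 scale), while the acid phosphatase gene pho1 fell from 815 ± 79 to 402 ± 8.8 CPM (-1.02, edgeR adjusted p = 0.000301). The phosphate transporter gene pho84 fell from 704 ± 50 to 235 ± 13 CPM (-1.58, edgeR adjusted p = 2.4e-05). Its upstream RNA prt2 had a log2 fold change of 0.08 (edgeR adjusted p = 0.0836). At the third locus nc-tgp1 rose by 0.38 and tgp1, a glycerophosphodiester transporter gene, by 1.21. The phosphate regulon thus had 1 gene higher and 2 lower of 3, too few for a list test. In the reference annotation nc-pho1 overlaps pho1 and prt2 overlaps pho84 on one strand, so the counts of these 4 features are uncertain. The gene fub2 follows pho1 on that strand. For the regulatory lncRNA list the camera adjusted p was 9.99e-08, and the adjusted p was 0.116 with an estimated correlation.

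**Figure D2:**
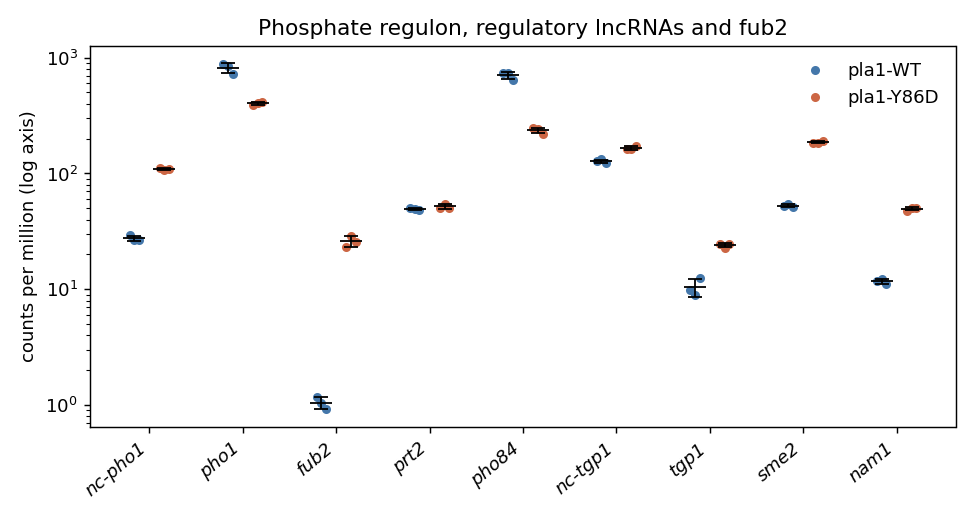
Read counts in CPM on a log axis for the phosphate regulon genes, the regulatory lncRNAs and fub2. Points are the 3 libraries of each strain, and bars show the mean and SD. The nc-pho1 RNA had means of 27.5 and 109.5 CPM, and pho1 had means of 815 and 402 CPM, in pla1-WT and pla1-Y86D.

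Annotated ncRNAs were shifted upward as a class. Of 1182 tested, 679 were higher and 226 lower, and 309 rose at least 2-fold against 227 of 4996 protein-coding genes. The odds of a call of at least 2-fold higher were 7.43 times those of protein-coding genes (95% interval 6.15 to 9.0, Fisher's exact test, adjusted p = 6.8e-97). For any higher call the odds ratio was 2.44 (95% interval 2.14 to 2.78) and for any lower call 0.269 (0.229 to 0.315). Calls of at least 2-fold lower were also more frequent in ncRNAs, 42 of 1182 against 104 of 4996, with an odds ratio of 1.73 (95% interval 1.17 to 2.52, Fisher's exact test, adjusted p = 0.00395). Among RNAs annotated as antisense, 402 were higher and 109 lower of 657. Intergenic RNAs had 177 higher and 104 lower of 378. Within the limits set for naming, SPNCRNA.1304, prl61, prl14 and ser2-antisense-1 had log2 fold changes of 4.11, 4.07, 3.27 and 3.20. The value of prl61 (SE 0.77) rests on control counts of 20, 1 and 3, and it was 6.05 without pla1-WT replicate 1 and 3.52 without pla1-WT replicate 2. That of SPNCRNA.1304 was 4.71 without pla1-WT replicate 1. SPNCRNA.1626 (-1.75), pof9-antisense-1 (-1.86) and SPNCRNA.291 (-1.82) fell. The ncRNA list had a camera adjusted p of 0.000428, and an adjusted p of 0.116 with an estimated correlation. The strand setting of the counting is not stated, which leaves some uncertainty in antisense counts.

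Small nucleolar and spliceosomal RNAs, which in mature form lack poly(A) tails, were higher in 29 and lower in 8 of 45 cases in these poly(A)-selected libraries. The snoRNA snR94 rose from 37.6 ± 1.1 to 268 ± 11 CPM (log2 fold change 2.83), snR33 rose by 1.63 and sno12 by 1.48. The camera adjusted p was 0.000385, and with an estimated correlation the adjusted p was 0.233. The share of counts on this class was 0.221% ± 0.0083 in pla1-WT and 0.297% ± 0.0089 in pla1-Y86D (SD, n = 3). For ncRNAs the shares were 1.44% ± 0.0085 and 1.74% ± 0.023. In both classes the strains' libraries did not overlap, and the exact permutation p was 0.1, the smallest this design allows. Every other class compared gave the same p. The share on rRNA went from 0.00915% ± 0.00034 to 0.0144% ± 0.00074, and that on tRNA from 0.00041% ± 8.4e-05 to 0.00088% ± 0.00013. The protein-coding share fell from 98.28% ± 0.0043 to 97.9% ± 0.031. A higher share was thus not particular to ncRNAs and snoRNAs.

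**Figure D3:**
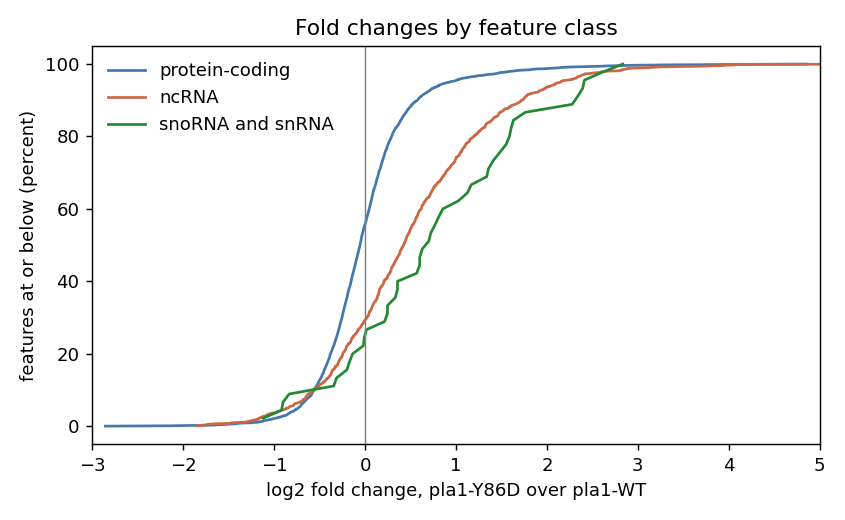
Cumulative percent of features (vertical axis) at or below each log2 fold change of pla1-Y86D over pla1-WT (horizontal axis), for tested protein-coding genes, ncRNAs, and snoRNAs with snRNAs. The medians were -0.05, 0.42 and 0.70, respectively. A few features lie outside the plotted range.

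The iron uptake list, written to include the regulator genes fep1 and php4, had 8 members higher and 2 lower of 11, with a median of 1.36. The siderophore transporter gene str1 rose from 27.3 ± 1.5 to 208 ± 7.1 CPM (log2 fold change 2.93), the iron oxidase gene fio1 rose by 1.57 and php4, a repressor of iron-using genes, by 0.80. Iron-using genes were lower in 10 of 12 cases, with leu2 at -1.24 and glt1 at -1.10. The catalase gene ctt1, which is also in the stress list, rose by 1.08. Camera adjusted p-values were 5.94e-06 for uptake and 0.000523 for iron-using genes. With an estimated correlation the adjusted p was 0.12 and 0.18.

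The core environmental stress list had 15 members higher and 5 lower of 22, with a median of 0.43. Besides hsp9 and ctt1, the metallothionein gene zym1 rose by 2.87 and the glutathione peroxidase gene gpx1 by 1.49. Its camera adjusted p was 1.4e-07, and the adjusted p was 0.139 with an estimated correlation. Heat shock chaperones had 6 higher and 7 lower of 15 (camera adjusted p = 0.379), with log2 fold changes of -0.65 for mcp60, -0.57 for mas5 and -0.55 for sti1.

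Ribosomal protein genes were lower in 95 and higher in 29 of 141 cases, with a median of -0.20. Single genes went further in both directions, with rps1401 at -1.32, rps1602 at -0.67 and rpl3002 at 1.14. Many ribosomal proteins have paired near-identical genes, which the counting can confuse. Ribosome biogenesis genes were lower in 17 and higher in 3 of 24 cases, among them nop2 (-0.78), nhp2 (-0.55) and rrp5 (-0.50). The camera adjusted p was 0.000435 for ribosomal proteins and 0.00721 for biogenesis. With an estimated correlation the adjusted p was 0.791 and 0.448.

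Cleavage and polyadenylation genes had 8 higher and 10 lower of 20, with ppn1 at -1.13, cft2 at -0.59 and seb1 at -0.34 (camera adjusted p = 0.572). In that list clp1 (-0.68) and hrp1 (-0.29) were matched by symbol to genes of a Cdc14-related phosphatase and a chromatin remodeller, and without them 8 were higher and 8 lower of 18 (camera adjusted p = 0.816). Of 27 genes for Mmi1, MTREC and exosome subunits, 5 were higher and 14 lower (camera adjusted p = 0.281). The cap-binding gene cbc1 (-0.79) and the exosome gene rrp46 (-0.68) fell, and red5, of MTREC, rose by 0.58. Regulators of inositol pyrophosphates and phosphate had 6 higher and 8 lower of 14 (camera adjusted p = 0.898). Their median was -0.19 although camera ranked them upward. The phosphodiesterase gene gde1 (0.79) and the 14-3-3 genes rad25 (0.55) and rad24 (0.51) rose.

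Nutrient and surface genes did not pass the list test. The glucose list, a mix of glucose repression, gluconeogenesis and hexose transporter genes, had 9 higher and 5 lower of 15 (camera adjusted p = 0.898). In it fbp1 was at 2.20, inv1 at 1.86 and mae2 at -2.10. The median of this list was 0.63 although camera ranked it downward. The uncalled member pck1 (0.06) is a protein kinase C gene, and without it the camera adjusted p was 0.897. Nitrogen starvation genes had 3 higher and 9 lower of 14 (camera adjusted p = 0.337), with ptr2 at -1.92, amt1 at -1.40 and isp6 at 1.14. Thiamine genes had 2 higher and 2 lower of 7 (camera adjusted p = 0.898), a median of 0.005 and a downward camera rank, with nmt1 at 2.15, bsu1 at 0.40 and pho4 at -0.47. Flocculation adhesins had 2 higher and 5 lower of 11 (camera adjusted p = 0.371), with pfl2 at -0.93, pfl3 at -0.90 and map4 at 0.39. Histone genes had 3 higher and 7 lower of 10 (camera adjusted p = 0.379), with hht1 at -0.55, hhf1 at -0.40 and hta1 at -0.29. The wtf family, which has near-identical copies, had 20 higher and 2 lower of 25 (camera adjusted p = 0.0744), with wtf20 at 1.47, wtf9 at 1.08 and wtf14 at 0.62. Of 4 tested Tf2 retrotransposons, which share reads, 3 were higher, Tf2-10 (0.53), Tf2-2 (0.37) and Tf2-11 (0.37). Under DESeq2 neither Tf2-2 (adjusted p = 0.054) nor Tf2-11 (adjusted p = 0.115) was called. Tf2-2 lost its call without pla1-Y86D replicate 3 (log2 fold change 0.29, edgeR adjusted p = 0.0872). Tf2-11 lost its call without pla1-WT replicate 1 (edgeR adjusted p = 0.0861), pla1-WT replicate 2 (0.0862) or pla1-Y86D replicate 3 (0.237).

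**Figure D4:**
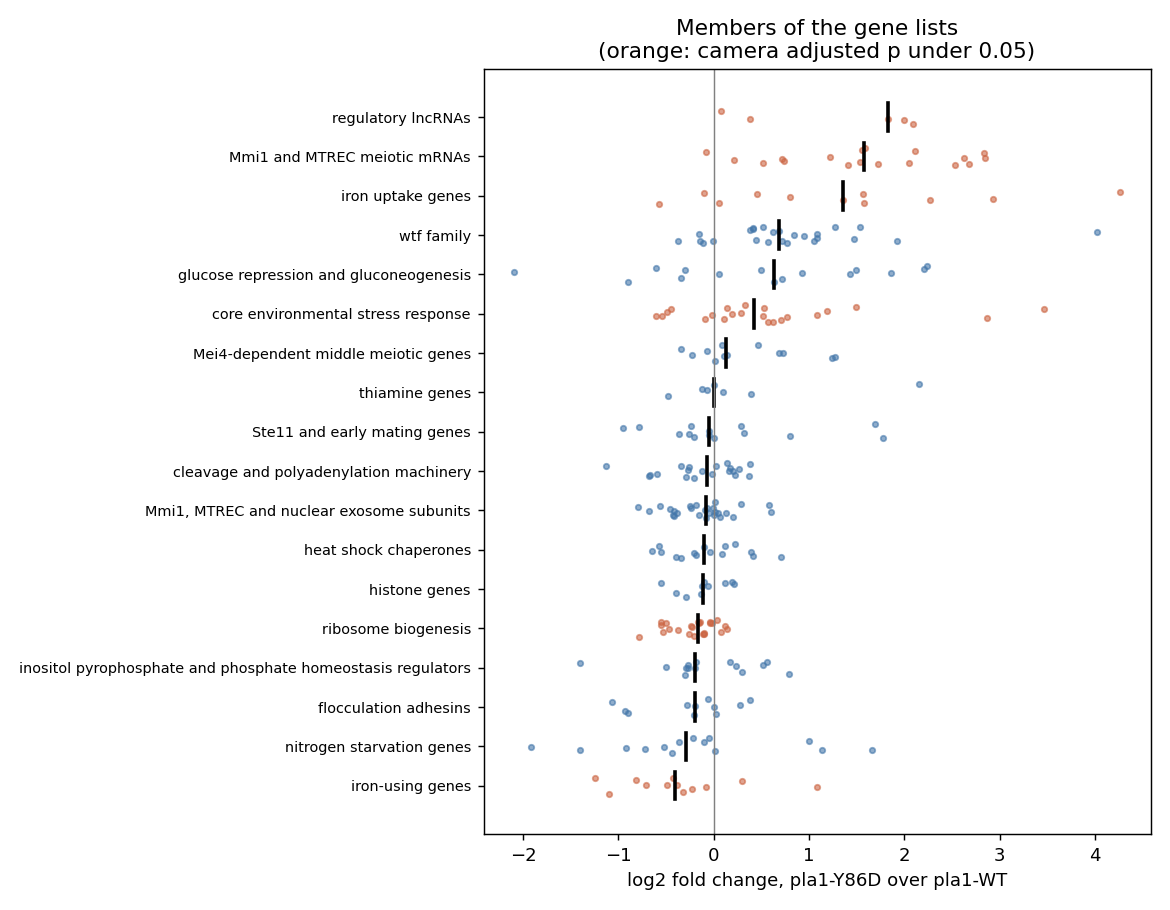
Log2 fold change of pla1-Y86D over pla1-WT (horizontal axis) for each tested member of the gene lists that had a list test, without the ribosomal protein, mug or meu, ncRNA and small RNA lists. Points are genes, vertical bars are list medians, and orange marks a camera adjusted p under 0.05 at the preset correlation. The medians were 1.57 for the Mmi1 and MTREC list and 0.12 for the middle meiotic list.

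Counts adjusted over the list alone equalled those over all genes tested, except for 8 heat shock genes lower and for ncRNAs, with 676 higher and 225 lower. In total 10 of the list tests passed at the preset correlation. With an estimated correlation camera passed 0 of 22 after adjustment and 6 at an unadjusted p under 0.05, while fry passed 19. At the preset correlation, divisions of the 6 libraries that mixed the strains also gave 6 to 11 list calls. The number of list calls at that setting therefore did not separate the real division from the mixed ones. Each mixed division retains part of the strain difference by construction. Its calls thus do not measure how often camera passes without any strain difference.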

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

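The alternatives were set before the data were examined, except the corrected lists, which were chosen after the values were seen and left each list on its side of the threshold. With protein-coding features alone 4111 were called of 4996 tested. In the other alternatives the count of called features stayed between 4684 and 5162. Over all of them the share of calls that were higher stayed between 46.7% and 50.1%. Every scaling was relative to the libraries' own counts, so a near-even split was largely set by it. A change shared by most mRNAs would not be seen. The log2 fold change of pla1 stayed between 0.35 and 0.43. Of 102 other named genes, 98 kept their direction and side of the threshold under each alternative run, and none reversed. The exceptions were tlh2, Tf2-2, Tf2-11 and prt2, which passed with a mean count of at least 50 (adjusted p = 0.0267). With DESeq2 the adjusted p was 0.054 for Tf2-2 and 0.115 for Tf2-11. With limma-voom the adjusted p of tlh2 was 0.0557. Most named genes were picked for a call in these same libraries. Their stability was therefore largely set by the choice and does not extend to all called features. Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.069, -0.029 and -0.059. The fit with the replicate block called 5057 features.

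List calls depended on the set test. With an estimated inter-gene correlation camera passed 0 of 22 lists (6 at an unadjusted p under 0.05). Adjusted p-values were then 0.0936 for Mmi1 and MTREC mRNAs, 0.116 for regulatory lncRNAs, ncRNAs and mug or meu genes, 0.12 for iron uptake, 0.18 for iron-using, 0.139 for core stress, 0.791 for ribosomal proteins, 0.448 for ribosome biogenesis and 0.233 for snoRNAs and snRNAs. Fry, which does not compare a list with other genes, called 19 lists. It added middle meiotic (0.00237), early mating (0.0274), cleavage and polyadenylation (0.00104), exosome subunits (0.000409), heat shock (0.0274), histone (0.00946), nitrogen (0.00233), flocculation (1.98e-05) and wtf genes (2.58e-05). Limma-voom added the wtf family (0.00471) and reversed the direction of 2 uncalled lists, inositol pyrophosphate regulators (0.818) and glucose genes (0.415); the cause was not tested.

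With protein-coding features alone, fewer features were tested: 329 changed at least 2-fold, 241 higher and 88 lower, 6 lists passed, and ribosome biogenesis had an adjusted p of 0.0616. Without the 20 most abundant features the share differences, mutant minus control, were 0.436 percentage points for ncRNAs and -0.551 for protein-coding genes. They were 0.00675 for rRNA and 0.102 for snoRNAs and snRNAs. With all features the differences were 0.301, -0.385, 0.00523 and 0.0752 in the same order. Taking an equal share of counts from both strains would enlarge all of them by a common factor. They did not grow equally, so a smaller total alone does not account for the change. In simulated data at this depth 82.0% of 1.2-fold changes were called among features with a mean count of at least 50. Smaller changes, and changes at lower counts, can be missed.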

Other observations

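The groups in this paragraph and the next were chosen after their values were seen. Glycolytic and fermentation genes took 11.9% ± 0.26 of the counts in pla1-Y86D and 8.41% ± 0.074 in pla1-WT (SD, n = 3 per strain, exact permutation p = 0.1, the smallest possible). Of 14 tested, 12 were higher and 1 lower by edgeR. The log2 fold changes were 1.02 for gpd3, 0.93 for tdh1, 0.88 for pgk1 and 0.55 for eno101, against -0.28 for pfk1, and hxk2 was at 0.01 (edgeR adjusted p = 0.851). Genes with proteasome in their product description were higher in 32 and lower in 10 of 46 cases.

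Of 6 genes of the UPF0300 family, 5 were higher, 4 at least 2-fold, and mug132 was lower at -0.29. Genes with tRNA ligase or tRNA synthetase in their product description, a match that took in trl1 and the cofactor gene asc1, were lower in 24 and higher in 8 of 37 cases, with a median of -0.25. Genes described as transmembrane transporters were lower in 87 and higher in 43 of 153 cases. The scalings tried left the median of all features between -0.03 and 0.02.

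The tests on meiotic cells, on UNAAAC hexamers, on ncRNAs inside opposite-strand genes and with mcp6 in place of hrs1 were chosen or changed after the results were seen. For the counts of changed features, the real division of the 6 libraries gave 5086 features and 714 at least 2-fold, and 1 of 10 divisions, the real one, reached these counts. The highest of the other divisions gave 0 by edgeR in both cases, with up to 13 features at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. For the list tests, 3 of the 10 divisions reached the real count of 10, and the highest other gave 11. With an estimated correlation 0 lists passed in the real division and in the others. Each mixed division retains part of the strain difference by construction, and the rest falls within its groups. That widens the spread within groups, so few or no called features were to be expected in mixed divisions. Their 0 calls therefore do not measure how many features would be called without any strain difference. With 10 divisions no share under 0.05 is possible.

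The higher level of Mmi1 and MTREC mRNAs was set against 3 explanations. After removal of a trend on GC content and transcript length, the list median was 1.5 (SD of members 0.92, 18 genes with the tRNA ligase gene hrs1), against 1.57 before, and the same with mcp6 in its place (SD 0.86), which argues against that trend as the whole cause. Meiotic cells in the culture would raise middle meiotic genes too, but the Mmi1 list median lay 1.45 above theirs (two-sided permutation test, p = 0.00038, or 0.00025 with mcp6), with control medians of 12.4 and 13.6 CPM; cells held in early meiosis stay open. The 14 members with an annotated 3' UTR carried 3.07 times (all 18 members 3.12 times) the UNAAAC hexamers, the motif Mmi1 binds, of length-matched genes, but all but hrs1 were picked as Mmi1 targets, so this cannot show the motif as the cause.

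Whether hexamers also mark genes outside the lists that were at least 2-fold higher was tested in 2 versions, and they differ. Only here, members of the mug or meu list counted as outside the lists and stayed in the set. The version run first, over all 184 transcripts, gave 1.10 times the hexamers of length-matched genes (permutation test by resampling, p = 0.024, adjusted p = 0.08 over 30 hexamer tests). Restricted to 149 transcripts with an annotated 3' UTR, the ratio was 1.01 (permutation test by resampling, p = 0.395). The restriction was made after the first value was seen, since a transcript without an annotated UTR is searched only in part. Of 1000 random sets, 68 fell under 0.05 in this test, and the question stays open. The narrower UUAAAC gave 1.33 times in all 184 transcripts (one-sided resampling test, adjusted p = 0.0066) and 1.24 times in the 149 (adjusted p = 0.08). It did not pass for all genes at least 2-fold higher outside the Mmi1 list, with 1.2 times in 214 transcripts (adjusted p = 0.08) and 1.1 times in 177 (adjusted p = 0.268), nor for the mug or meu genes among them (ratios 1.04 and 0.525). Genes at least 2-fold lower had 1.22 times in all transcripts (one-sided resampling test, adjusted p = 0.08). Higher and lower genes were not compared directly, so an excess of UUAAAC was not shown to be particular to higher genes.

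The upward shift of ncRNAs was weighed against counting. Sense reads counted on antisense RNAs at the same rate in both strains would raise both partners. The sense partners of 169 antisense RNAs at least 2-fold higher had a median log2 fold change of -0.15 (95% bootstrap interval -0.21 to -0.07). This argues against such counting at an equal rate, but a rate that differed between the strains cannot be seen by this test. Low counts alone are argued against as well: with a mean count of at least 50 the odds ratio for a higher call was 2.49 (95% interval 2.15 to 2.88). Of the ncRNAs, 158 lie wholly inside a protein-coding gene of the opposite strand, and their median mean count was 79.2, as would be seen if reads of opposite strands were separated in the counting, though the setting itself is not stated. A real rise of ncRNAs in pla1-Y86D, or of their poly(A)-tailed fraction, remains a hypothesis that these libraries cannot divide.

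Features at least 2-fold higher lay next to each other in 74 pairs, 1.48 times the mean of permuted orders (permutation p = 0.0002). Without pairs whose annotated spans overlap the ratio was 1.64 (permutation p = 0.0005), which argues against reads shared within annotated overlaps. Reads that run past an annotated end onto a neighbour were not tested. Features within 100 kb of a chromosome end rose at least 2-fold in 26.1% of 211 cases, against 8.3% elsewhere (Fisher's exact test, p = 8.37e-14), and fell at least 2-fold in 5.7% against 2.3% (p = 0.00413). Without them the ratio was 1.26 (permutation p = 0.0403), between the bounds set in advance, so location near the ends may account for part of the pairing and stays open.

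For protein-coding genes alone, a test read after its values were seen, 32 pairs gave a ratio of 3.11 (permutation p = 0.0001, the smallest possible). Without features near the ends 20 pairs gave 2.63 (permutation p = 0.0001), which argues against the ends as the whole cause for these genes. Without overlapping pairs as well the ratio was 3.36.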
